A study of Mus musculus with 13 samples.

How the data were processed

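The series holds 13 mouse samples from epididymal white fat of Adipoq-NuTRAP animals on the C57BL/6J background, fed chow or a high-fat diet (HFD) for 10 weeks. In these animals, per the labels' protocols, ribosomes of adipocytes are recovered from whole-fat homogenate with an antibody against GFP (translating ribosome affinity purification, TRAP), and adipocyte nuclei are sorted on mCherry. The 6 RNA libraries, 3 per diet, were analysed. The 5 chromatin samples for the histone mark H3K27ac (3 chow and 2 HFD) and the 2 for PPARG (1 per diet) were not analysed here. RNA was depleted of ribosomal RNA, tagmented with a kit that does not mark strand, and sequenced on a HiSeq2500, per the labels' protocols.

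The submitters' processing notes name HISAT2, Picard, featureCounts and edgeR beside tools for the chromatin data (Bowtie2, SAMtools, MACS2, bedtools and HOMER) and the mouse genome build mm10; roles and versions are not given in the sources used here. The deposited values are log2 CPM (read counts scaled by library size) per gene, rounded to 2 decimals, 1 column per library, with gene rows that join a transcript identifier and a symbol. That the scale is log2 was read from the values: they run below 0, their anti-logs sum to between 984422 and 1182123 per library, and the anti-logs of low values lie on steps of whole reads. The authors' filter on low genes and the size of their prior count are not given in the sources used here. CPM values were relative to an effective library size, since the anti-log totals differ between libraries.

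The design fixed before the data were examined assumed linear CPM, so each value was turned back into CPM as a power of 2 and log2(CPM + 1) was tested as planned. Fold changes are HFD minus chow on that scale, which understates the change of low genes. Of the 11761 listed genes, the 11643 with a mean of at least 1 CPM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The threshold carried no bound on fold change. No unmapped column of values was present, and each column was matched to a sample by its diet and replicate number.

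Steps between low values gave each library's effective size: 23200000, 32400000 and 7430000 reads for chow replicates 1, 2 and 3, and 33600000, 32000000 and 39400000 reads for HFD replicates 1, 2 and 3. All low values used (under 20 reads) came out whole in every library, within 0.1 of a read. A single read was therefore worth 0.135 CPM in chow replicate 3 and 0.0254 to 0.0431 CPM in the others, and a level of 3 reads corresponded to 0.404 CPM and to 0.0761 to 0.129 CPM. These limits cover counting error only. Because the deposited unit is a log value, the count tests planned for recovered reads were not run; limma's voom weights on the recovered reads were used as an added alternative.

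Before the data were examined, 41 gene lists were fixed from textbook knowledge: adipocyte identity and function, metabolism, TGF-beta-SMAD signalling and matrix, inflammation and stress, cell cycle, ribosomal proteins, and markers of other cell types of fat. The 37 lists with at least 3 tested members were tested with limma's camera (competitive, preset correlation of 0.01), adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives; fry is self-contained, so it tests a list against no change and not against the other genes. The epididymis and mitochondrially encoded lists had 0 tested members, and the neutrophil and mast cell list and the erythroid list had 2 each, so these 4 were not tested. The share of the CPM total taken by 11 lists was compared with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 against 3.

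The rule for named genes, also fixed before the data were examined, took the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 10 CPM and no overlap between diets, leaving out predicted symbols. It added, from each list, the 2 risen and 2 fallen members with the largest change, and a fixed set whatever their result: Pparg, Cebpa, Adipoq, Fabp4, Slc2a4, Lep, Ucp1, Tgfb1, Tgfbr1, Smad3, Ccl2, Adgre1, Cd68 and Col6a3. Ucp1 was not among the listed genes. This gave 130 genes, of which a selection is named; some results the rule covers are not reported here. Positions are from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes, in which 10981 listed symbols were found. In that annotation 47 of the 130 named genes overlap another gene, 7 of them a gene that is also listed (Ebf2, Nnat, Tpi1, Pfkfb1, Eng, Ddit3 and Mcm7). Overlap was taken over whole gene spans. Where exons overlap, reads cannot be told apart without strand, and whether exons do was not checked. Genes with close relatives or processed copies, such as Gstm1 and the ribosomal protein genes, are uncertain too, since reads of the copies may be counted for them.

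The gene test and list test were tested on simulated data with the libraries' means and depths, in which 200 of 11632 genes tested were changed. At adjusted p under 0.05 the test recovered 54% of genes changed 2-fold and 88% of those changed 4-fold. Of 149 calls, 7 (4.7%) were false. Far fewer genes were changed than the 35.1% called in the real data, so these rates need not carry over. Genes were drawn independently, whereas the estimated correlation within a list reached 0.68 (mesothelial markers). The simulation therefore did not check camera's preset correlation. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, the threshold, a replicate block and each library left out in turn. Figures were drawn with matplotlib 3.10.9.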

Results

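Polysome-bound RNA was recovered by TRAP from adipocytes of epididymal white fat of mice fed chow or HFD for 10 weeks, with 3 libraries per diet. The series title asks what obesity does to adipocyte identity, the activity of the nuclear receptor PPARG and TGF-beta-SMAD signalling, and the comparison of HFD with chow addresses this in RNA. The effective library size was 23200000, 32400000 and 7430000 reads in chow replicates 1, 2 and 3, and 33600000, 32000000 and 39400000 reads in HFD replicates 1, 2 and 3. Chow replicate 3 was the shallowest, with 117 genes at the lowest value of the table against 0 to 7 in the others, and it held the most residual ribosomal RNA (Rn45s, 23170 CPM against 4068 to 12503 CPM, chosen after its values were seen). The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

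HFD changed a large part of the RNA in the adipocyte pulldown, whose cell of origin was not settled by these values. The strongest falls included Cyp2f2, a cytochrome P450 gene, from 128 ± 39.6 CPM in chow to 1.52 ± 0.659 CPM in HFD (SD, n = 3 each), and Gpx3, a secreted glutathione peroxidase, from 506 ± 59.8 to 33.2 ± 8.38 CPM. The strongest rises included Slc5a7, a choline transporter, from 0.297 ± 0.101 to 114 ± 63.1 CPM, and Mrc2, a collagen-binding endocytic receptor, from 5.92 ± 1.65 to 215 ± 81.5 CPM. Leptin (Lep), the hormone of fat mass, rose from 1224 ± 231 to 5497 ± 856 CPM.

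With limma and Benjamini-Hochberg adjustment, 4084 of 11643 genes changed, 2221 higher and 1863 lower in HFD (54.4% higher). Of these 4084 genes, 1326 rose and 424 fell by at least 1 on the log2 scale. The diets' libraries did not overlap for 50.2% of all tested genes, where chance gives 10%, and for 4045 of the 4084. Correlations between libraries, across genes, which are not independent replicates, were 0.974 to 0.984 within a diet and 0.899 to 0.918 between diets. Rescaling each library to the same total over the listed genes gave 2515 higher and 1334 lower genes (65.3% higher) and moved the median of all genes by 0.10. Setting the median adipocyte identity gene equal between libraries, a scaling chosen after seeing the data, gave 4682 higher and 408 lower genes (92.0% higher) and moved the median of all genes by 0.45. Changes below are therefore relative to the bulk of genes, which the deposited scaling holds near 0 (median log2 fold change -0.004). Without HFD replicate 3 the count of lower genes was 1162. The excess of higher genes did not hold in every setting. Quantile normalization gave 1986 higher and 2293 lower genes (46.4% higher). Testing only genes with a mean of at least 5 CPM gave 1771 higher and 1775 lower genes (49.9% higher).

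The 8 highest log2 fold changes belonged to Slc5a7 (6.31 ± 0.36 SE), the membrane protease gene St14 (5.65), Wisp2 (5.64), the urea-cycle enzyme gene Ass1 (5.48), the orphan receptor gene Gpr50 (5.02), Mrc2 (4.93), the macrophage elastase gene Mmp12 (4.84) and the serotonin-synthesis gene Tph2 (4.78). Their limma adjusted p-values (Benjamini-Hochberg) lay between 1.04e-06 for St14 and 0.000118 for Tph2. Their order depends on the pseudocount: with the deposited log2 values used directly Gpr50 (10.7) and St14 (9.53) stood above Slc5a7 (8.47), as did Ass1 (9.20) and Mmp12 (8.80). Several rest on very few chow reads, 0 to 2 per library for Gpr50, 0 to 4 for St14 and 3 to 8 for Slc5a7. The spread among HFD libraries was wide for Tph2 (68.5 ± 59.5 CPM) and Gpr50 (39.1 ± 30.2 CPM). Among the 8 lowest were Cyp2f2 (-5.67 ± 0.26 SE), the methyltransferase gene Inmt (-5.64), the angiopoietin gene Angpt1 (-4.68), Mycl (-4.47), Gpx3 (-3.91), Bmper (-3.83) and Fam13a (-3.62). Their limma adjusted p-values lay between 3.72e-06 for Cyp2f2 and 3.19e-05 for Inmt. On GRCm38.p6, Slc5a7 lies on chromosome 17 at 54273590 to 54299038 and Lep on chromosome 6 at 29060221 to 29073876.

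**Figure D1:**
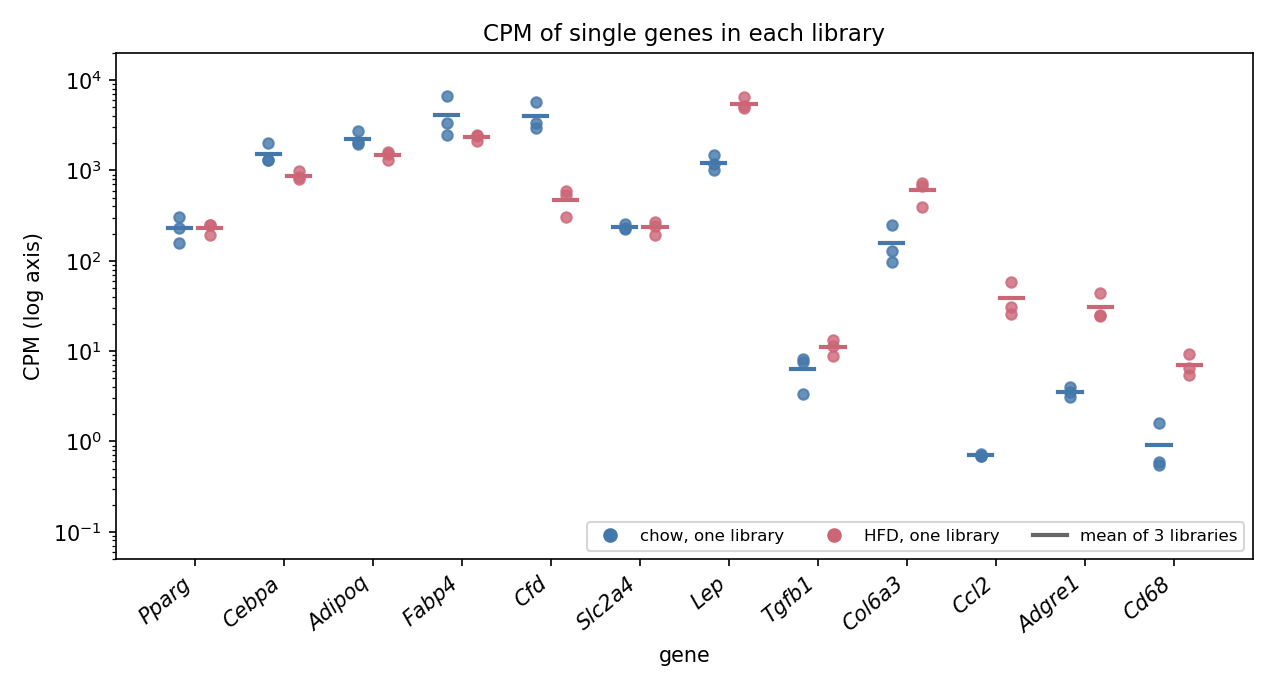
CPM (vertical log axis) of 12 genes (horizontal axis) in each of the 3 chow and 3 HFD libraries; points are libraries and lines the mean of 3. Cfd was lower and Lep, Ccl2 and Adgre1 higher in all 3 HFD libraries than in any chow library, while Pparg and Slc2a4 overlapped.

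Genes of adipocyte identity were lower on balance in HFD, but with opposite movements among them. Cfd (the secreted complement factor adipsin) fell from 4020 ± 1513 to 476 ± 148 CPM, and Adrb3, the beta-adrenergic receptor typical of fat, from 1339 ± 319 to 335 ± 98.5 CPM (SD, n = 3). Cebpa, a master factor of fat cell differentiation, fell from 1537 ± 394 to 880 ± 89.7 CPM, whereas its partner Pparg stood at 232 ± 74.5 in chow and 231 ± 33.0 CPM in HFD. Orm1, an acute-phase protein gene, and Gpd1, which makes glycerol phosphate for triglycerides, rose by 2.76 and 1.27 on the log2 scale.

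Of 33 tested identity genes, 15 fell and 4 rose over all genes, with the same 15 and 4 when adjusted over the list alone, and 14 did not pass. The list's median log2 fold change was -0.35, below 0 under every scaling except that to the median identity gene, where it was 0.13 against 0.45 for all genes. Camera gave an adjusted p of 0.0062, and adjusted p = 0.57 with an estimated correlation. Quantile normalization ended this call (0.11). With limma, Cebpa had a log2 fold change of -0.78 (SE 0.19, adjusted p 0.0116) and Adipoq, the adiponectin gene, -0.60 (SE 0.18, adjusted p 0.0254). Under scaling to the median identity gene neither passed (Cebpa -0.30, adjusted p 0.11; Adipoq -0.13, adjusted p 0.474). That scaling is set by this list itself, Cebpa and Adipoq included. Smaller falls of the list and its members under it are therefore built in. The Adipoq call was also lost without HFD replicate 1, 2 or 3 (adjusted p 0.0594, 0.0571 and 0.112). Fabp4, the fatty acid carrier, differed by -0.70 (SE 0.31, limma adjusted p 0.112), with a wide spread in chow (4150 ± 2176 CPM), and passed without chow replicate 2 (adjusted p 0.0255). The log2 fold change was 0.04 (SE 0.23, limma adjusted p 0.915) for Pparg and -0.04 (SE 0.15, adjusted p 0.857) for the insulin-responsive glucose transporter gene Slc2a4; their 3 libraries per diet do not exclude small differences. On GRCm38.p6, Pparg lies on chromosome 6 at 115360879 to 115490404 and Cebpa on chromosome 7 at 35119293 to 35121928.

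Among 33 genes listed as PPARG targets, 7 rose and 9 fell (7 and 10 adjusted over the list alone), and the list was not called (camera adjusted p 0.44). Its median was -0.21, and 0.26 after scaling to the median identity gene. The lipid droplet gene Plin2 (1.67) and the fatty acid carrier gene Fabp5 (1.83) rose, while Slc27a1, a fatty acid transporter gene, fell by 1.11 on the log2 scale (-0.63, adjusted p 0.0516, under that scaling). Pck1, of glyceroneogenesis, fell by 1.11 and lost its call without HFD replicate 3 (limma adjusted p 0.0666). Of 21 transcription factors of fat cell differentiation, 10 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.42 that was 0.06 under scaling to the median identity gene. Camera called the list (adjusted p 0.0051), with adjusted p = 0.26 with an estimated correlation. Ebf2 (-2.03), whose gene overlaps a listed predicted gene, and Nfia (-1.19) fell, whereas Zfp423 (1.23) and Klf4 rose.

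The adipokine list had 7 risen and 8 fallen genes of 21 (8 and 8 adjusted over the list alone; camera adjusted p 0.89). Lep (2.17) and Sfrp5 (4.09), a secreted Wnt-binding protein gene, rose, and Cfd (-3.07) and angiotensinogen (Agt, -1.85) fell. Of 13 genes tied to fat expansion, 7 rose and 2 fell over all genes and adjusted over the list alone, with a median of 1.27 (camera adjusted p 0.014; adjusted p = 0.27 with an estimated correlation). Camera on ranks ended this call (0.052). The 2 that fell were Cyp2e1 (-3.37), a cytochrome P450 gene, and Nnat (-1.04), which lies within a listed gene. Beside these changes, markers of macrophages, endothelium and smooth muscle were higher in HFD (values below).

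**Figure D2:**
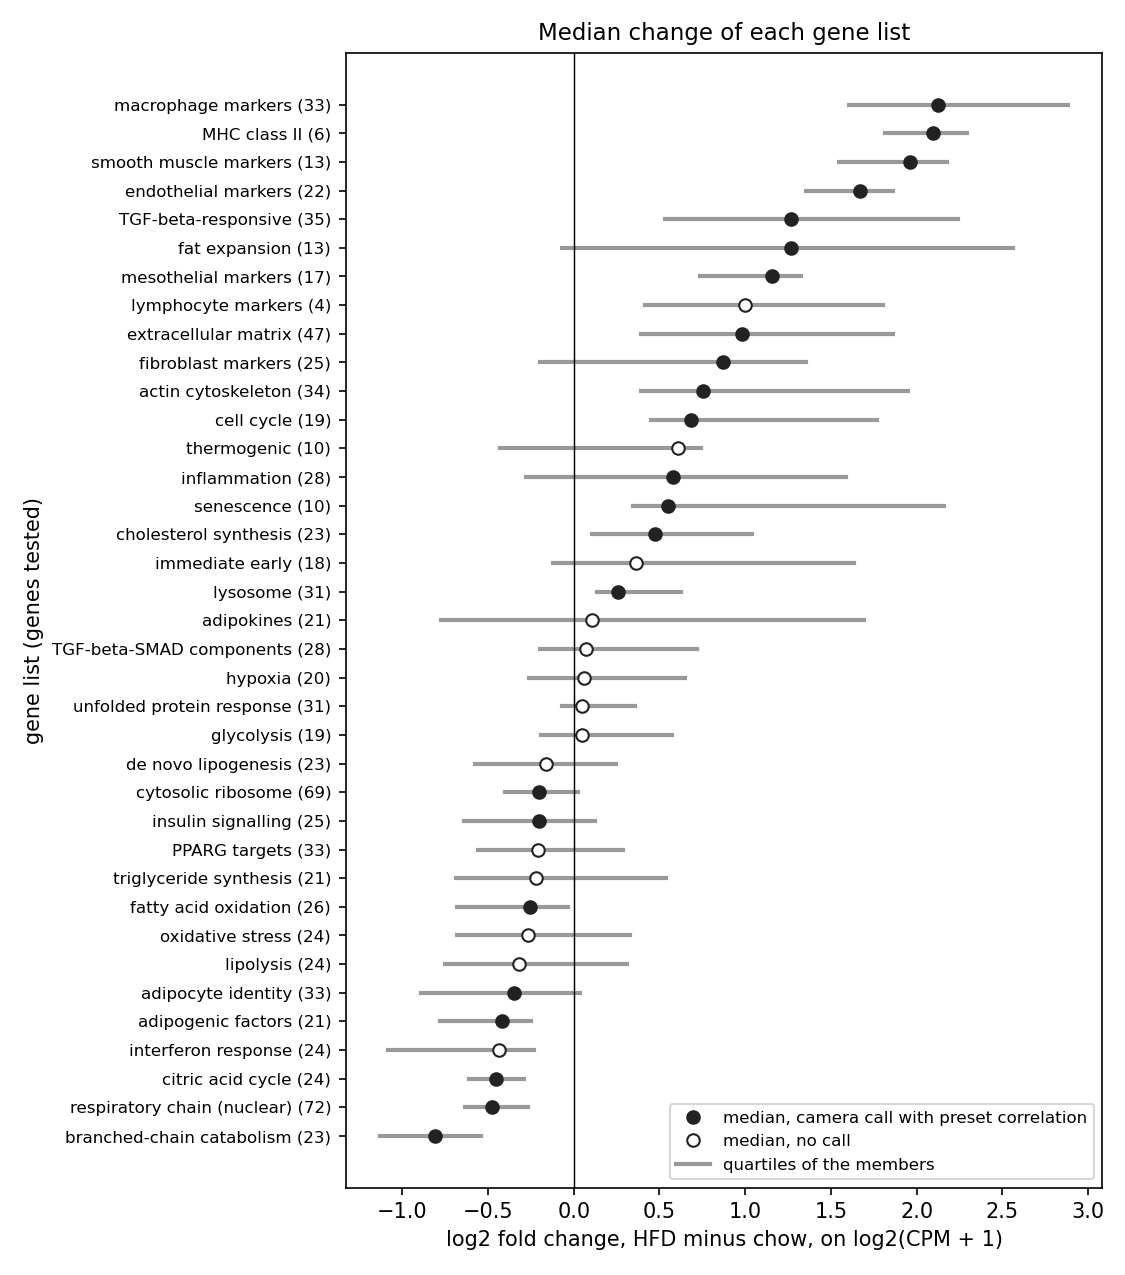
Median log2 fold change, HFD minus chow on log2(CPM + 1) (horizontal axis), of the 37 tested gene lists (vertical axis, genes tested in parentheses); grey lines are quartiles of the members and filled points lists called by camera with the preset correlation. Medians run from -0.81 for branched-chain amino acid catabolism to 2.12 for macrophage markers. After scaling to the median adipocyte identity gene, 12 of the 14 medians below 0 lay above 0. Those 12 still lay below the median of all genes, which was 0.45 under that scaling. The medians of branched-chain catabolism and of the respiratory chain stayed below 0.

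Genes of mitochondrial metabolism were lower in HFD, and the breakdown of branched-chain amino acids stood out. Of its 23 tested genes 19 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.81. Ivd, the isovaleryl-CoA dehydrogenase of leucine breakdown, fell from 475 ± 47.6 to 147 ± 13.3 CPM, and Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, from 124 ± 34.9 to 42.9 ± 1.97 CPM (SD, n = 3). Of 72 nuclear genes of the respiratory chain, 33 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -0.47. Of 24 genes of the citric acid cycle, 13 fell and 1 rose (17 and 2 adjusted over the list alone).

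Camera called the branched-chain list with an adjusted p of 1.5e-10, and adjusted p = 0.22 with an estimated correlation. Under scaling to the median identity gene 9 of its genes fell, with a median of -0.34. The respiratory chain list had a camera adjusted p of 3.2e-08, and adjusted p = 0.53 with an estimated correlation, while fry, which tests a list against no change and not against other genes, gave 0.072; under the same scaling 3 of its genes fell, 4 rose and the median was -0.005. The citric acid cycle list had a median of -0.45 (0.02 under that scaling) and a camera adjusted p of 7.1e-05, with adjusted p = 0.41 with an estimated correlation. Sdha, a subunit of succinate dehydrogenase in both lists, fell by 1.00 and Suclg2 by 1.13, whereas Idh3a rose by 0.62. Of 26 genes of fatty acid oxidation, 10 fell and 4 rose (11 and 4 adjusted over the list alone), with a median of -0.26 that was 0.22 under scaling to the median identity gene. Camera called this list (adjusted p 0.0098), with adjusted p = 0.41 with an estimated correlation, and quantile normalization ended the call (0.077). Acot2 and the mitochondrial coactivator gene Ppargc1a fell by 1.53 and 1.00 (Ppargc1a -0.60, adjusted p 0.122, under scaling to the median identity gene), and Cpt1b, which brings fatty acids into mitochondria, rose by 1.51 from 1.03 to 4.77 CPM.

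Genes of lipid and glucose handling went both ways. De novo lipogenesis had 4 risen and 5 fallen genes of 23 (4 and 6 adjusted over the list alone; camera adjusted p 0.35), with a median of -0.16 that was 0.31 under scaling to the median identity gene. The desaturase gene Scd2 rose by 2.15, and Acacb, an acetyl-CoA carboxylase gene, and Aacs fell by 2.32 and 1.59 on the log2 scale. Scd1, a more abundant desaturase gene of the list (chosen after its values were seen), was lower in all HFD libraries. It stood at 22227, 14563 and 30153 CPM in chow and 12944, 11747 and 11747 CPM in HFD. Triglyceride synthesis had 6 risen and 6 fallen of 21 (6 and 7 adjusted over the list alone; camera adjusted p 0.60). Its median was -0.22 (0.25 under scaling to the median identity gene) and its mean 0.01, with Mogat2 up by 3.96 and the acyltransferase genes Gpam and Gpat4 down by 1.35 and 1.30. Of 24 lipolysis genes, 4 rose and 10 fell, over all genes and adjusted over the list alone, without a call (camera adjusted p 0.060) and with a median of -0.32 that was 0.16 under scaling to the median identity gene. The list was called without chow replicate 2 (0.022), with equal totals (0.037) and under that scaling (0.025). Receptor genes that curb lipolysis went both ways: Hcar1 fell by 2.07, and Ptger3 (1.93) and Adora1 (1.41) rose.

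Of 25 genes of insulin signalling, 10 fell and 4 rose (10 and 5 adjusted over the list alone), with a median of -0.20 that was 0.27 under scaling to the median identity gene. Irs1, the main docking protein of the insulin receptor, fell from 439 ± 27.8 to 136 ± 9.39 CPM, and Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, from 1405 ± 371 to 465 ± 60 CPM, whereas Tusc5, which aids recycling of glucose transporters, and Ptprf rose by 0.72 and 0.84. Camera gave this list an adjusted p of 0.042, and adjusted p = 0.40 with an estimated correlation. The call was lost without chow replicate 3 (0.079), with quantile normalization (0.26), at a mean of at least 5 CPM (0.075), on ranks (0.054), with voom weights (0.053) and under scaling to the median identity gene (0.07). Glycolysis had 6 risen and 2 fallen genes of 19 (7 and 3 adjusted over the list alone; camera adjusted p 0.41), with Pfkfb4 up by 2.35 and Hk2 down by 0.68 (-0.20, adjusted p 0.285, under scaling to the median identity gene). The thermogenic list had 4 risen and 3 fallen of 10 (5 and 3 adjusted over the list alone; camera adjusted p 0.41).

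Genes that respond to TGF-beta were higher in HFD, while the components of the pathway as a group were not called. The cell-cycle inhibitor gene Cdkn1a rose from 8.28 ± 0.885 to 151 ± 16.1 CPM and the matrix gene Postn from 3.41 ± 1.69 to 52.6 ± 8.59 CPM (SD, n = 3). Of 35 TGF-beta-responsive genes, 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 1.27. Tgfb1 itself, the ligand gene, stood at 6.39 ± 2.61 CPM in chow and 11.1 ± 2.19 CPM in HFD and did not pass.

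The responsive list had a camera adjusted p of 2.5e-09, and adjusted p = 0.22 with an estimated correlation. With limma, Tgfb1 had a log2 fold change of 0.77 (SE 0.30, adjusted p 0.0714), the receptor gene Tgfbr1 0.03 (SE 0.12, adjusted p 0.849) and the signal transducer gene Smad3 0.24 (SE 0.15, adjusted p 0.231). Tgfb1 passed without chow replicate 1 (adjusted p 0.0408), with a replicate block (0.0378) and under scaling to the median identity gene (0.0168), under which Smad3 (0.71, adjusted p 0.0159) and Tgfbr1 (0.505, adjusted p 0.0452) passed too. Under that scaling the median of all genes was 0.45 and that of the pathway's components 0.53. Passing there is therefore not by itself a rise relative to other genes, and Tgfbr1 lay near the median of all genes. Of 28 components of TGF-beta-SMAD signalling, 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p 0.44). The activin-binding gene Fst (2.09) and Eng (1.60), a co-receptor gene that is also an endothelial marker here, rose, and the receptor genes Acvr1c (-1.06) and Tgfbr3 (-0.97) fell.

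Of 47 matrix genes, 28 rose and 1 fell (30 and 2 adjusted over the list alone), with a median of 0.98 (camera adjusted p 1.8e-07; adjusted p = 0.30 with an estimated correlation). Col6a3, a collagen abundant in fat, rose from 158 ± 79.2 to 601 ± 177 CPM and Col12a1 from 5.24 ± 0.849 to 85.5 ± 42.8 CPM. The single fall was Dcn, the decorin gene, from 290 ± 45.4 to 83.6 ± 25.5 CPM. Of 34 actin cytoskeleton genes, 23 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.76 (camera adjusted p 2.5e-09; adjusted p = 0.22 with an estimated correlation). Acta2, the smooth muscle actin gene, rose by 3.18 and Lcp1, a leukocyte actin-bundling gene, by 3.31. The matrix and actin lists moved together with markers of smooth muscle (median 1.96) and of fibroblasts (median 0.87). This is partly built in, since the lists share genes. Acta2 is also on the smooth muscle list, and Dcn is on the fibroblast list.

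Markers of other cell types were higher in HFD at low levels, macrophage markers most of all. Adgre1, the F4/80 antigen gene, rose from 3.55 ± 0.482 to 31.2 ± 11.1 CPM, Cd68 from 0.915 ± 0.596 to 7.09 ± 2.06 CPM, and the lysosomal membrane gene Gpnmb from 2.55 ± 0.656 to 76.9 ± 51.6 CPM (SD, n = 3). Of 33 macrophage markers, 30 rose and 1 fell (32 and 1 adjusted over the list alone), with a median of 2.12. The exception was Cd14, which fell from 14.2 ± 2.61 to 2.28 ± 0.772 CPM. The chemokine genes Ccl2 and Ccl7 rose by 4.45 and 4.21 on the log2 scale.

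The macrophage list had a camera adjusted p of 1.7e-15, and adjusted p = 0.27 with an estimated correlation. All 6 tested genes of antigen presentation by MHC class II rose, over all genes and adjusted over the list alone, with a median of 2.09 (camera adjusted p 5.3e-05; adjusted p = 0.22 with an estimated correlation); Cd74 rose by 2.34. Of 22 endothelial markers 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.67 (camera adjusted p 1.3e-07; adjusted p = 0.41 with an estimated correlation), Pecam1 from 5.24 ± 2.21 to 29.9 ± 12.2 CPM. Of 13 smooth muscle markers 12 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 1.96 (camera adjusted p 1.7e-06; adjusted p = 0.22 with an estimated correlation). Of 17 mesothelial markers 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.15 (camera adjusted p 0.00035; adjusted p = 0.52 with an estimated correlation; fry 0.051). Of 25 fibroblast and progenitor markers 10 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.87. Camera gave the fibroblast list an adjusted p of 0.048, and adjusted p = 0.60 with an estimated correlation, and the call was lost under most alternatives: without chow replicate 3 (0.11), HFD replicate 1 (0.09) or HFD replicate 3 (0.13), and with changes of pseudocount (0.1, 0.053) or filter (none 0.057, at least 5 CPM 0.06). It was also lost with equal totals (0.12), quantile normalization (0.092), scaling to the median identity gene (0.54), voom weights (0.076), ranks (0.054) and the deposited values used directly (0.054). Serpinf1 (4.20) and Pdgfrb (2.52) rose, and Gsn, which was abundant in chow at 8616 CPM, fell by 1.28. The 4 tested lymphocyte markers had 2 risen genes (3 adjusted over the list alone) and no call (camera adjusted p 0.073), but the list was called without HFD replicate 3 (0.026). Of 28 inflammation genes 12 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.58 (camera adjusted p 0.013; adjusted p = 0.22 with an estimated correlation; 0.05 and no call under scaling to the median identity gene).

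Markers of most other cell types took small shares of each library. Macrophage markers took 0.0156 ± 0.00282% of the CPM total in chow and 0.0832 ± 0.0226% in HFD (SD, n = 3; exact permutation p = 0.1, the smallest possible). Endothelial markers took 0.0108% and 0.0440%, smooth muscle markers 0.0410% and 0.138%, and mesothelial markers 0.0541% and 0.101%. The mesothelial difference of 0.0473 percentage points was 0.0205 without HFD replicate 3 and 0.0129 without C3, its most abundant gene. Fibroblast markers went the other way, from 1.38 ± 0.221% to 0.876 ± 0.171%, of which most was Gsn. Adipocyte identity genes took 5.74 ± 0.787% in chow and 4.36 ± 0.268% in HFD, respiratory chain genes 1.26 ± 0.138% and 0.907 ± 0.0676%, branched-chain genes 0.593 ± 0.0511% and 0.335 ± 0.00851%, and matrix genes 1.62 ± 0.173% and 2.50 ± 0.332%. Libraries of the diets did not overlap in any of these 9 shares (exact permutation p = 0.1 each, adjusted p 0.122 over the 11 shares). TGF-beta-responsive genes, at 0.720 ± 0.123% and 1.04 ± 0.170%, and ribosomal protein genes, at 0.362 ± 0.0447% and 0.322 ± 0.0325%, overlapped between diets (exact permutation p = 0.2 each). The ribosomal difference of -0.0396 was -0.0646 without chow replicate 1 and -0.0216 without chow replicate 3.

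**Figure D3:**
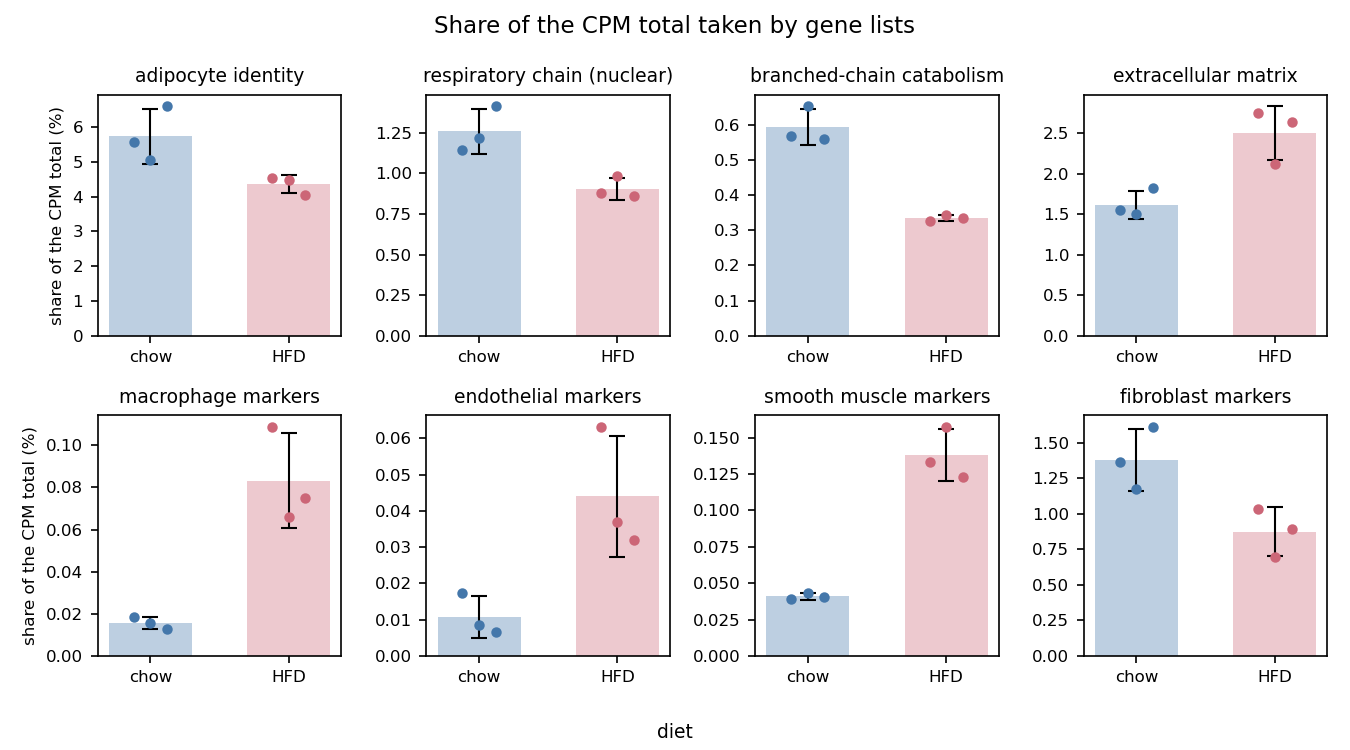
Share of the CPM total in percent (vertical axes, from 0) of 8 gene lists in chow and HFD libraries (horizontal axis); bars are means, error bars SD, points the 3 libraries per diet. Macrophage markers reached 0.0832% in HFD against 0.0156% in chow, and adipocyte identity genes 4.36% against 5.74%.

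In all, camera with the preset correlation called 23 of the 37 lists, 15 higher and 8 lower. With an estimated correlation it called 0, with 7 at an unadjusted p under 0.05, while fry called 25 and camera on ranks 20. Fry asks another question than camera, whether a list differs from no change, so its results are not calls gained or lost by camera. Of the lists camera called, fry did not call the identity (0.06), respiratory chain (0.072), ribosomal protein (0.36), fibroblast (0.072) and mesothelial (0.051) lists. Of the others it called adipokines, thermogenic and lymphocyte genes and oxidative stress (0.047 each), glycolysis and hypoxia (0.023 each) and immediate early genes (0.007).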

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

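Alternatives were fixed before the data were examined except 3 chosen after seeing the data: deposited log2 values used directly, voom weights on recovered reads, and scaling to the median adipocyte identity gene. The planned edgeR and DESeq2 tests on recovered reads were not run, because the deposited unit is log2. Over all alternatives, 2390 values for named genes, 653 for lists, 76 counts and 73 shares kept their result. The other 73 values for named genes, 86 for lists, 7 counts and 4 shares did not. A count was taken as kept when it lay within a fixed factor of the main one. The counts with quantile normalization, where lower genes outnumbered higher ones, therefore stand among the 76. A bound of 1 on log2 fold change left 1750 genes (1326 higher, 424 lower). Leaving out each library gave 1162 to 1740 lower genes, the lowest without HFD replicate 3, 2850 to 3783 changed genes and 20 to 26 called lists. Scaling to the identity gene gave 4682 higher and 408 lower genes. The identity list had adjusted p 0.11 with quantile normalization, 0.57 with an estimated correlation and 0.06 with fry (main 0.0062, otherwise 0.00059 to 0.021). The TGF-beta-responsive list had 0.22 with an estimated correlation (otherwise at most 0.0015), and 0 lists were called with it. Values that turned direction, none past the threshold in either fit, were adjusted p 0.87 for adipokines and 0.42 for thermogenic genes at a mean of at least 5 CPM; 0.81 for adipokines at equal totals; 0.70 for PPARG targets, 0.96 for lipogenesis and 0.70 for triglyceride synthesis with quantile normalization; 0.60 for triglyceride synthesis with fry; and 0.34 for adipokines and 0.85 for thermogenic genes under identity scaling. Slc2a4 turned to 0.071 at equal totals, 0.063 with quantile normalization and 0.435 under identity scaling. Leaving out each library gave -0.21 to 0.26 for Pparg, -0.14 to 0.10 for Slc2a4, -0.008 to 0.076 for Tgfbr1, and adjusted p 0.76 to 0.92 for adipokines and 0.017 to 0.60 for the interferon list, which turned direction without chow replicate 2. Without its most abundant gene, the HFD minus chow share was 0.0795 percentage points for smooth muscle, 0.0129 for mesothelial, -0.0666 for fibroblast and -0.216 for branched-chain genes. The cause was not tested. With a replicate block, 4839 genes were called (2594 higher, 2245 lower) and 23 lists. Same-number correlations of deviations were 0.43, 0.23 and 0.09, and each HFD library correlated best with the chow library of its number. Chow replicate 3, however, correlated better with HFD replicate 2 (0.15) than with HFD replicate 3 (0.09). Whether the numbers pair the libraries therefore stays open, and the main test used no block. Depth limits low genes most in chow replicate 3, where 1 read is 0.135 CPM.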

Other observations

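Genes of the cell cycle, senescence, cholesterol synthesis and lysosomes were higher on balance in HFD. Of 19 cell-cycle genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.68 (camera adjusted p 0.00035; adjusted p = 0.33 with an estimated correlation). The proliferation marker Mki67 rose from 1.06 ± 0.0541 to 20.3 ± 9.23 CPM and Top2a, the DNA topoisomerase of dividing cells, by 2.59. Macrophage and endothelial markers rose beside them (30 of 33 and 20 of 22), and the dividing cells were not identified. Of 10 senescence-related genes 5 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.55 (camera adjusted p 0.0010; adjusted p = 0.22 with an estimated correlation). Its largest rises were Mmp12 (4.84), a protease gene that is also on the macrophage list, and Cdkn1a (4.03), which halts the cell cycle. Of 23 cholesterol synthesis genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p 0.0023; adjusted p = 0.41 with an estimated correlation), led by Insig1 (1.67) and Dhcr7 (1.41). Of 31 lysosomal genes 12 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 0.26 (camera adjusted p 0.0023; adjusted p = 0.45 with an estimated correlation). Its top members Gpnmb (4.25) and Ctss (3.68) are also on the macrophage list, which rose beside it.

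Several stress lists went both ways without a call. Oxidative stress defence had 4 risen and 8 fallen genes of 24 (4 and 9 adjusted over the list alone; camera adjusted p 0.084; median -0.27, and 0.19 under scaling to the median identity gene), with Gpx3 (-3.91) and Gsta4 (-1.84) down and Hmox1 (1.81) up, and was called without chow replicate 1 (0.022) or HFD replicate 3 (0.038) and under that scaling (0.025). The unfolded protein response had 6 risen and 3 fallen of 31, over all genes and adjusted over the list alone (camera adjusted p 0.35), with Atf3 (2.54) and Ddit3 (1.56), which overlaps a listed gene, up, and Xbp1 (-0.93) and Asns (-1.10) down. Hypoxia had 9 risen and 3 fallen of 20 in both counts, the latter adjusted over the list alone (camera adjusted p 0.42), with Lox up by 1.27 and Ndrg1 down by 1.65. Immediate early genes had 8 risen and 4 fallen of 18 in both counts, the latter adjusted over the list alone (camera adjusted p 0.052), with Fos up by 3.23 and Myc down by 1.00; the list was called without chow replicate 1 (0.034) or HFD replicate 2 (0.028) and at a mean of at least 5 CPM (0.025). Under scaling to the median identity gene Xbp1 (-0.45, adjusted p 0.0655) and Myc (-0.62, adjusted p 0.0962) did not pass. Of 69 ribosomal protein genes 1 rose and 6 fell (0 and 0 adjusted over the list alone), with a median of -0.20 that was 0.25 under scaling to the median identity gene (camera adjusted p 0.028; adjusted p = 0.75 with an estimated correlation); the call was lost without chow replicate 3 (0.21), HFD replicate 1 (0.13) or HFD replicate 3 (0.051), at a mean of at least 5 CPM (0.06), with voom weights (0.076), and under that scaling (0.11), and fry, which tests against no change, gave 0.36.

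Interferon-response genes were highest in 1 chow library. Of 24 interferon genes 2 rose and 1 fell between diets (1 and 1 adjusted over the list alone; camera adjusted p 0.22). In chow replicate 2 Iigp1, an interferon-induced GTPase gene, stood at 734 CPM against 3.41 and 8.34 CPM in the other chow libraries, and Gbp2 at 714 CPM against 54.2 and 63.1 CPM (both chosen after their values were seen). Of the 24 genes, 21 were highest among chow libraries in replicate 2, where 27.8% of all tested genes were. Among HFD libraries replicate 2 was the highest, with Iigp1 at 74 CPM against 13.5 and 9.13 CPM. Camera called the list lower without chow replicate 1 (0.017) and under scaling to the median identity gene (0.0026), while without chow replicate 2 its direction turned to higher (0.60, no call). Prtn3, chosen after its values were seen, lies on chromosome 10 at 79879667 to 79883174 of GRCm38.p6, close to Cfd at 79890853 to 79892655, and held 0.541% to 1.46% of the CPM of Cfd in the 6 libraries.

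The tests weighed from here on were all chosen after the results were seen. For the counts of calls, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many called genes (4084; highest other split 0) and 1 gave as many called lists (23; highest other split 20). With 10 splits a share under 0.05 cannot be reached. Each other split sets 2 chow and 1 HFD library against 1 chow and 2 HFD. Its 8 to 20 list calls therefore still carry part of the diet difference and are no null. The diet difference also widens the spread within its groups, so its 0 called genes are no null either.

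The measure behind the list shifts was itself revised once, after its first values were seen. It was first the median log2 CPM of a list's genes in each library, which jumps between genes of different level, and was replaced by the median of each gene's deviation from its own mean. The first measure gave 1.43 ± 0.26 (SE) for macrophage against other markers, -0.55 ± 0.36 for fibroblast and 0.023 ± 0.39 for smooth muscle markers against TGF-beta-responsive genes, and -0.31 ± 0.085 for respiratory chain against ribosomal protein genes. These 4 readings were the same with both measures. Against adipocyte identity genes it gave 0.51 ± 0.16 for the respiratory chain and 0.00 ± 0.16 for branched-chain genes, and for both the reading depends on the measure. For the respiratory chain the first has a smaller fall than that of identity genes, by over 3 SE. A dilution equal for both does not give this, but dilution by cells that carry respiratory chain transcripts could. The second measure (0.018 ± 0.106) has an equal fall. For branched-chain genes the first measure left dilution as a full account of the fall, and the second (-0.346 ± 0.133) left it undecided.

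Markers of other cell types were higher in HFD. A lower adipocyte share would raise the markers of every other type alike only if adipocytes expressed none of them, which was not tested. Macrophage markers with chow means under 50 CPM shifted by 1.21 ± 0.21 (SE, log2) more than the mean of the endothelial, fibroblast, mesothelial and smooth muscle medians. The bound was set on chow values, which are part of the comparison, so it favours genes low in chow and can raise such shifts. With genes on a second marker list left out too, it kept all 33 tested macrophage markers but 16 of 25 fibroblast markers. Single shifts were 2.905 ± 0.309 for macrophage and 2.23 ± 0.354 for smooth muscle markers. They were 1.93 ± 0.502 for endothelial, 1.329 ± 0.468 for mesothelial and 1.282 ± 0.374 for fibroblast markers. The contrast therefore does not decide on a lower adipocyte share. The shallow chow replicate 3 was not the source of the macrophage shift, since the list's median was 1.94 without it and 2.12 with it. RNA of macrophages in the pulldown and expression of macrophage genes by adipocytes on HFD were not tested apart, and both stay open.

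TGF-beta-responsive genes were higher in HFD. Low-baseline responsive genes held by no marker list shifted by 1.93 ± 0.18 (SE, log2, 19 genes). The bound on chow values can raise this shift too. All 35 tested responsive genes had a median of 1.27 on log2(CPM + 1). The 14 fibroblast markers outside the TGF-beta and matrix lists with chow means under 50 CPM, a bound that leaves out the abundant Gsn, which fell, shifted by 0.55 ± 0.32 less (difference -0.55). This is within 3 SE, so RNA of fibroblasts in the pulldown and a response of adipocytes cannot be told apart with these markers and 3 libraries per diet. Smooth muscle markers outside the TGF-beta, matrix and actin lists shifted by as much (difference 0.067 ± 0.39), so RNA of smooth muscle cells may contribute. A response of adipocytes to the diet stays open beside both, as untested.

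Genes of branched-chain breakdown and the respiratory chain were lower in HFD. Identity genes shifted by -0.477 ± 0.135 (SE, log2). Dilution of adipocyte RNA by RNA of other cells was taken to lower the lists by no more than that. This bound holds if identity genes are expressed in adipocytes alone and do not change there, which was not tested. The fall of the lists would be smaller if the other cells carried their transcripts too. The respiratory chain shift differed from that of identity genes by 0.018 ± 0.11. With this measure dilution stays open for the respiratory chain. If the bound holds, that requires other cells to carry few of its transcripts, which was not tested. Pparg and Slc2a4 (0.04 and -0.04) were not lower and Gpd1 rose. The branched-chain genes shifted by a further -0.35 ± 0.13, within 3 SE, where the measure used first gave no difference, so for them dilution and a change within adipocytes cannot be told apart at 3 libraries per diet. Respiratory chain genes shifted by -0.24 ± 0.05 relative to ribosomal protein genes, which were chosen as short abundant transcripts. The ribosomal protein genes shifted by -0.222 ± 0.171 themselves and took a smaller share in chow (0.362% against 1.26%). A loss of short abundant transcripts in HFD libraries that differs in degree between these sets could give this, so it stays open. A change with diet in adipocytes stays open beside it, as untested.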
